A study of Mus musculus with 16 samples.

How the data were processed

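RNA was measured in CD31-positive endothelial cells sorted by flow cytometry from whole mouse embryos at embryonic day 9.5, with libraries made by tagmentation, per the labels' protocols. The 16 libraries carried 6 Notch1 genotypes. The labels spell the wild-type genotype differently for replicate 1 and for replicates 2 and 3, and these were taken as 1 group. The labels do not say whether a library held 1 embryo or several, so the p-values measure the spread between libraries, which may be partly technical.

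The authors deposited 1 table per library with 28107 RefSeq transcripts and, for each, an FPKM value, a coverage value and a status, in the layout of cufflinks, per the file headers. Reads were aligned with TopHat2 2.0.9 to mm9, per the submitters' processing notes. The cufflinks version, the read length and the strandedness are not given in the sources used here. The deposited FPKM values are fragments per kilobase of transcript, scaled to the number of mapped fragments, so they are not counts and no count test was used. Where reads fall on overlapping genes or on near-identical copies, the estimates of those genes are uncertain. The deposited coverage values are mean read depths over a transcript. Within each library, coverage divided by FPKM was 1 constant, with a relative spread of at most 2.31e-05, and this constant is the aligned sequence in gigabases. It was 0.189 for 1 +/− library (replicate 2), 0.262 for the 12/vg library, and between 1.11 and 1.80 for the other 14. Counts per gene were not recovered, so no counting interval is given, and low FPKM values in the shallow libraries have the least precision.

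Transcript FPKM values were summed over each of 22096 gene symbols with Python 3.11.15 and pandas 2.3.3. The 211 symbols with any transcript whose status was not OK in any library were left out, of which 87 had a mean FPKM of at least 1. Genes with a mean FPKM of at least 1 over all libraries were tested, 10550 in number. Each library was divided by a median-ratio factor over the 8638 genes with FPKM of at least 1 in every library. Values were analysed as log2(scaled FPKM + 1), so a fold change is on that scale and understates the change of low genes.

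Each of 10 comparisons was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend=TRUE, two-sided). All 16 libraries entered the fit in 6 groups, which gives 10 residual degrees of freedom. The trend over the number of wild-type Notch1 alleles was fitted as a slope. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene was called at an adjusted p under 0.05. A set of 28 gene lists was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 573 list entries, 569 were matched to symbols in the files, through synonyms of a RefSeq table where needed. Notch1 and Notch2 by allele were compared with exact permutation tests, two-sided. The test of Notch1 within the low range of library numbers was added after the results were seen.

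Named genes follow a rule. Per comparison, Notch1 and Notch2 are looked at, and the 10 largest rises and 10 largest falls among called genes are named, with libraries of the compared groups not overlapping (a condition not applied to the interaction, the trend and the mean of groups), without predicted genes and pseudogenes. Up to 4 called members of each list are added. Where fewer than 5 genes were called, the 3 rising and 3 falling genes with the smallest p are given as values that did not pass. A gene that this rule names in +/vg against +/− is not reported here. Genes that mark embryo sex were left out, since sex is not in the labels. The groups, the tests of the 10 comparisons, the lists, this rule and most alternatives were fixed before the data were examined. The alternatives were other scalings, pseudocounts and filters, other moderation and weights, a covariate for the library number, leaving out haemoglobin genes (no gene symbol in the files starts with mt-), and leaving out each replicate. Chosen after seeing the data were leaving out the 2 shallow libraries, a depth covariate, keeping genes of another status, and leaving out genes with no transcript of 300 nt or more (341 of the genes tested).

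The file names carry a library number, between 203 and 248 for 9 libraries and between 371 and 380 for 7. The labels name no batch. All +/+ libraries were in the high range, all +/12, 12/vg and 12/− libraries in the low range, and +/− and +/vg held 2 high and 1 low each. A covariate for this range, fitted beside the groups, is therefore estimated from +/− and +/vg alone, with 1 low library each. Their high libraries include the shallow +/− replicate 2. The fit was tested on simulated data made from the real means and residual spreads of the 10550 genes for 12/− against +/12. It recovered 74 of 100 genes changed by 1 on the log2 scale and 90 of 100 changed by 2, all with the right sign, and called 12 unchanged genes. The simulated values were independent between genes and had the same spread in every library. Unequal depth, the library number range and correlation between genes were therefore absent, and the recovery holds for such data only. Coordinates are those of the files (mm9), written from 1.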

Results

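Expression was measured in endothelial cells of day 9.5 mouse embryos that carried different pairs of Notch1 alleles, to ask how Notch1 dose affects endothelial gene expression. Notch1 is a receptor whose intracellular domain is released by cleavage and acts in the nucleus. The alleles were wild type (+), a null allele (−), an allele called vg whose released domain is less stable, and an allele called 12, in which the Notch2 intracellular domain replaces that of Notch1. The labels describe endothelial development as normal in +/+, +/−, +/vg and +/12 embryos (3 libraries each), as partly impaired in 12/vg (1 library) and as impaired in 12/− (3 libraries). Between 9975 and 10538 genes per library had an FPKM of at least 1. Pearson's r between log2 profiles across genes, which are not independent replicates, ran from 0.897 to 0.925 within groups and from 0.887 to 0.933 between groups among libraries above 1 gigabase. No pair of libraries was a duplicate.

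The alleles were checked first in the transcripts of the edited gene. Notch2 (chromosome 3, 97817461 to 97954290, mm9) was higher in the 7 libraries with a 12 allele, at 4.10 ± 0.357 scaled FPKM (SD, n = 7), than in the 9 without one, at 2.68 ± 0.482 (SD, n = 9), with an exact permutation p of 2.6e-04 and an adjusted p of 0.0021 over 8 such tests. Carriers ran from 3.39 to 4.41 and the others from 2.10 to 3.41. Within the low file numbers the 7 carriers averaged 4.10 and the 2 others 2.25 (exact p = 0.028, the smallest that 36 arrangements can give, adjusted p = 0.056). Notch1 (chromosome 2, 26313422 to 26359342) was lower with a 12 allele, at 16.2 ± 1.66 against 20.6 ± 2.47 (exact permutation p = 0.0017, adjusted p = 0.0070, n = 7 and n = 9). All carriers of the 12 allele lie in the low range of file numbers and 7 of the 9 others in the high range, and within the low range Notch1 averaged 16.2 and 21.8 (exact p = 0.028, adjusted p = 0.056, n = 7 and n = 2). With a null allele Notch1 averaged 18.5 against 18.8 without one (exact permutation p = 0.88), so the FPKM of the whole gene did not tell the null allele from the others. The part of Notch1 removed in the null allele is not given in the sources used here.

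**Figure D1:**
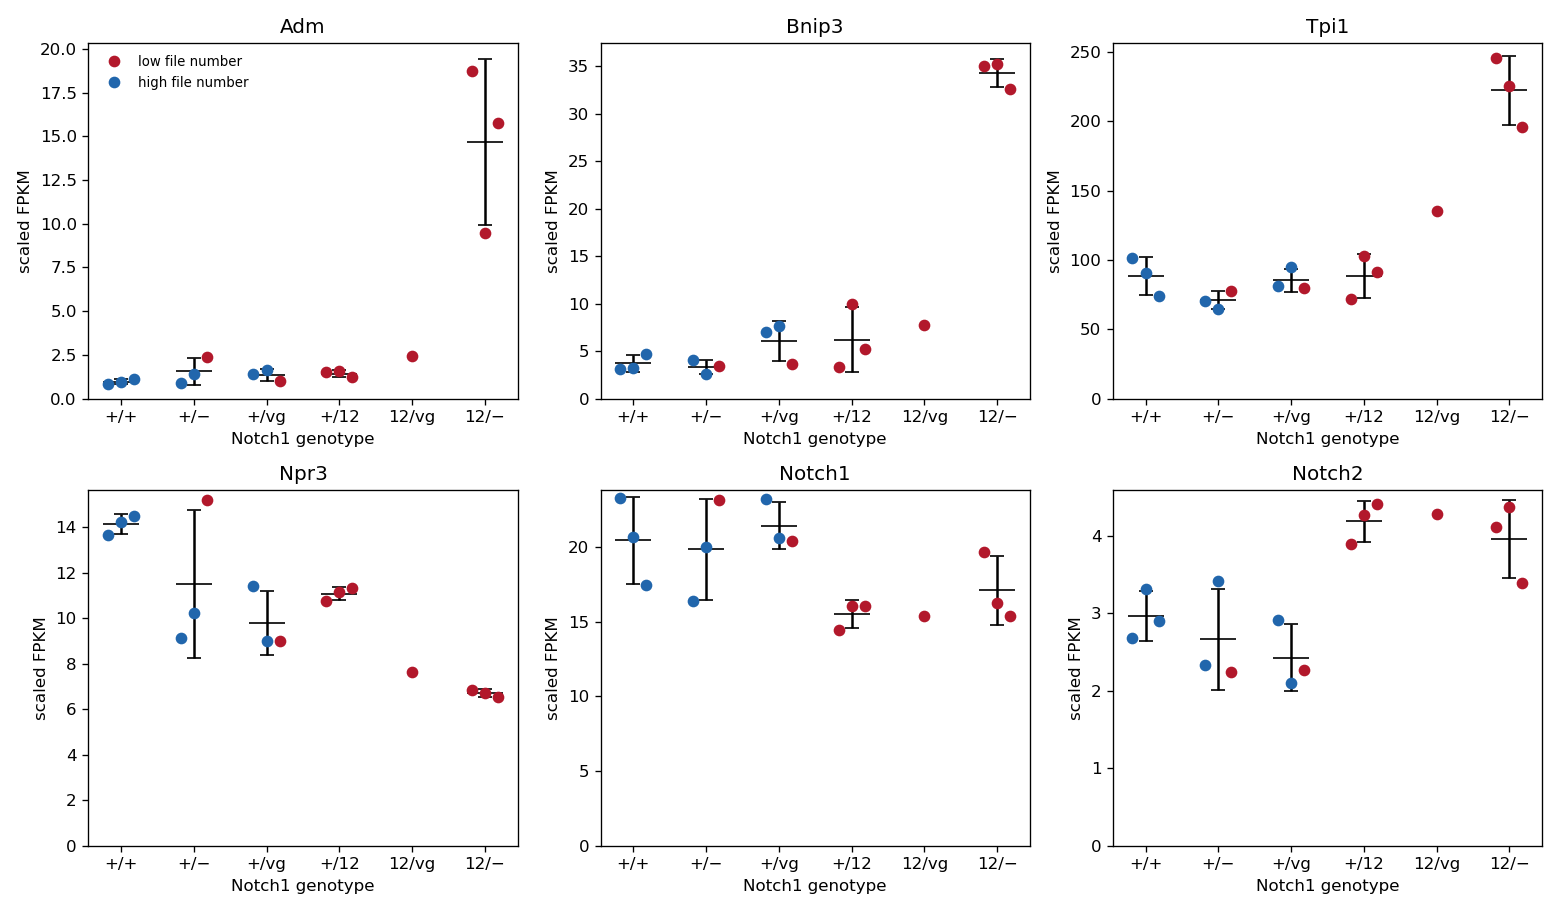
Scaled FPKM (vertical axis) of 6 genes in each library by Notch1 genotype (horizontal axis), where points are libraries coloured by file number range and bars are means with SD for groups of 3. Adm, Bnip3 and Tpi1 were higher in all 3 12/− libraries than in every other library, and Npr3 was lower there than in every other library.

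The comparison of 12/− with +/12 asks what the loss of the remaining wild-type allele does beside a 12 allele. Genes of hypoxia and glycolysis were higher in 12/− embryos. Adm, which encodes the vasodilator peptide adrenomedullin (chromosome 7, 117771183 to 117773333), rose from 1.44 ± 0.181 to 14.7 ± 4.74 scaled FPKM (SD, n = 3 each), a log2 fold change of 2.64 ± 0.24 (SE, limma adjusted p = 6.9e-04). Bnip3, a mitophagy receptor, rose from 6.21 ± 3.40 to 34.3 ± 1.47, by 2.40 ± 0.30 (limma adjusted p = 0.0032). The glycolytic enzyme Tpi1 rose from 88.5 ± 15.6 to 222 ± 24.8, by 1.33 ± 0.16 (limma adjusted p = 0.0025), and the endoplasmic reticulum oxidase Ero1l rose by 1.16 ± 0.12 (limma adjusted p = 0.0015). Vegfa, the endothelial growth factor, rose from 0.849 ± 0.142 to 3.13 ± 0.863 (limma adjusted p = 0.0255). Of the 27 hypoxia and glycolysis genes tested, 8 were called higher, 0 lower and 19 were not called. Adjusted over the list alone, 25 were higher. All 27 had a positive fold change, with a median of 0.94 (camera adjusted p = 6.3e-52, and adjusted p = 0.0025 with an estimated correlation).

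Other genes with large rises were Ndufa4l2, a mitochondrial complex subunit homologue (log2 fold change 2.10 ± 0.25), Cav1, the main protein of caveolae (1.88 ± 0.25), the transcriptional repressor Bhlhe40 (1.81 ± 0.24), the secreted glycoprotein Stc2 (1.73 ± 0.26), the potassium channel subunit Kcne3 (1.71 ± 0.23), the prolyl hydroxylase Egln3 (1.70 ± 0.24) and the matrix protein Sparcl1 (1.58 ± 0.20), with limma adjusted p-values from 0.0025 to 0.013. In total 22 genes were higher and 0 lower in limma, with 349 higher and 209 lower at an unadjusted p under 0.05.

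Among the other lists, tip cell and sprouting genes were higher as a set, with a median log2 fold of 0.39 over 20 genes (camera adjusted p = 8.3e-10, and adjusted p = 0.14 with an estimated correlation). Adm was its 1 called member, and 6 were higher when adjusted over the list alone. Basement membrane genes had a median of 0.28 (camera adjusted p = 8.4e-06, and adjusted p = 0.33 with an estimated correlation), with Sparcl1 called. The pan-endothelial list had a median of 0.25 (camera adjusted p = 9.2e-06, and adjusted p = 0.24 with an estimated correlation), with 0 of 27 called and 1 adjusted over the list alone. Endocardial genes had a median of -0.25 (camera adjusted p = 0.0047, and adjusted p = 0.33 with an estimated correlation). Cholesterol synthesis genes had a median of -0.32, with 0 of 16 positive (camera adjusted p = 9.2e-06, and adjusted p = 0.33 with an estimated correlation). The BMP and TGF-beta list and the VEGF list passed at camera adjusted p = 0.046 each, and gave adjusted p = 0.49 and adjusted p = 0.35 with an estimated correlation. The VEGF list did not pass with the number range as a covariate (camera adjusted p = 0.0599). Notch targets had a median of 0.16 over 21 genes, with 0 called in limma (camera adjusted p = 0.60). Notch1 and Notch2 differed by 0.13 ± 0.15 and -0.07 ± 0.15 on the log2 scale (SE, limma adjusted p = 1.0 each).

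Over the alternatives run, Vegfa, Stc2 and Egln3 were called in 14 of 21, 16 of 21 and 17 of 22, with log2 folds of at least 1.00, 1.60 and 1.49. Bnip3, Bhlhe40, Kcne3 and Tpi1 lost their call with the groups compared fitted alone, and Ndufa4l2 at a pseudocount of 0.1. Their folds were at least 2.09, 1.59, 1.52, 1.19 and 2.04 in every alternative run. Without 12/− replicate 1 the count of called genes was 10, without 12/− replicate 3 it was 14, and without +/12 replicate 3 it was 13. With the groups compared fitted alone it was 8, of which 5 were among the 22, and with array weights it was 92.

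**Figure D2:**
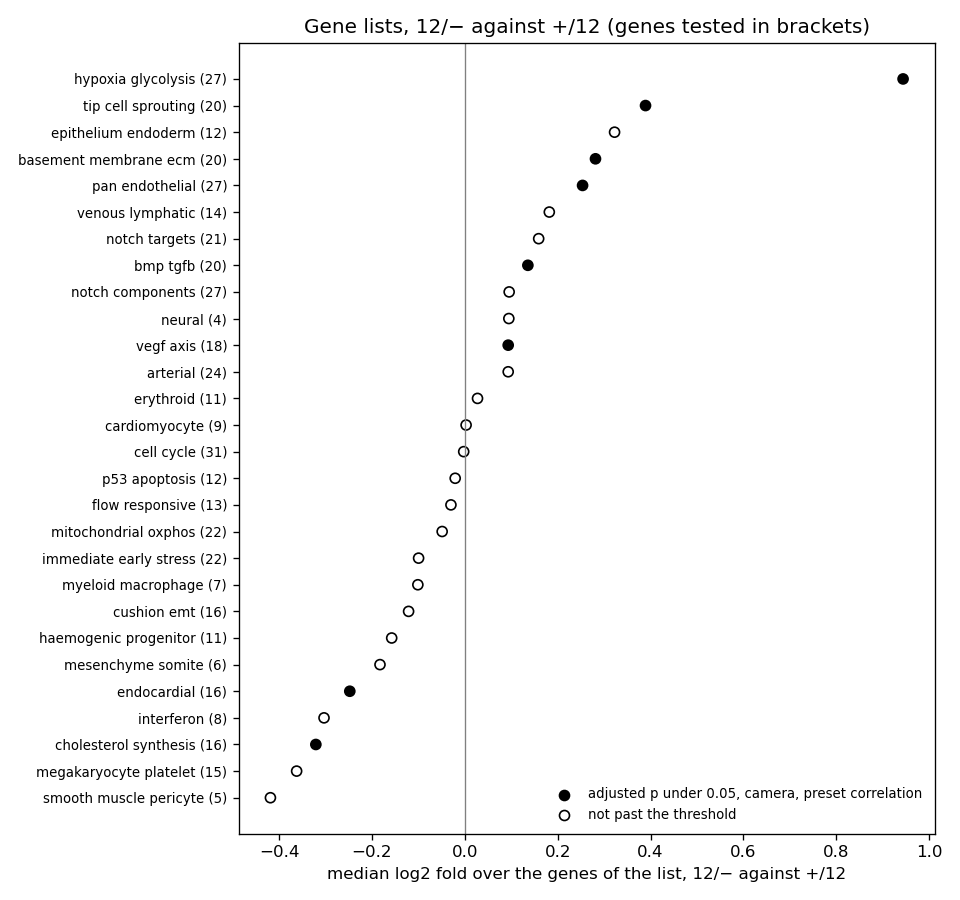
Median log2 fold change between 12/− and +/12 libraries (horizontal axis) for each of 28 gene lists (vertical axis, with the number of genes tested), filled where camera's adjusted p with the preset correlation was under 0.05. The hypoxia and glycolysis list has the highest median, at 0.94.

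Against +/+, the 12/− embryos showed the same kind of rise and several falls. Adm rose by 2.94 ± 0.24 on the log2 scale (SE, limma adjusted p = 1.9e-04) and Bnip3 by 2.92 ± 0.30 (limma adjusted p = 3.5e-04). Bhlhe40 rose by 2.56 ± 0.24, Cav1 by 2.53 ± 0.25, the ankyrin repeat gene Ankrd37 by 2.40 ± 0.33, Ndufa4l2 by 2.38 ± 0.25, Sparcl1 by 2.21 ± 0.20, Kcne3 by 2.10 ± 0.23, Ndrg1 by 2.07 ± 0.40 and Egln3 by 2.00 ± 0.24, with limma adjusted p-values from 2.5e-04 to 0.039. Of the 27 hypoxia and glycolysis genes, 14 were called higher and 27 were higher adjusted over the list alone (median 1.11, camera adjusted p = 1.5e-36, and adjusted p = 0.010 with an estimated correlation). Flt1, a VEGF receptor, rose from 26.6 ± 2.54 to 48.4 ± 3.03 scaled FPKM (n = 3 each, limma adjusted p = 0.024), and the TGF-beta signalling inhibitor Smad7 from 4.01 ± 0.504 to 7.49 ± 0.354 (n = 3 each, limma adjusted p = 0.017).

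Npr3, a natriuretic peptide receptor of the endocardium, fell from 14.1 ± 0.434 to 6.70 ± 0.168 scaled FPKM (SD, n = 3 each), a log2 change of -0.97 ± 0.15 (SE, limma adjusted p = 0.011). The matrix protein gene Frem1 changed by -0.81 ± 0.13, the axon guidance ligand Slit2 by -0.75 ± 0.15, the cyclin Ccnd2 by -0.72 ± 0.12, the lipid kinase Pik3c2b by -0.70 ± 0.11, the cytokine receptor Lifr by -0.70 ± 0.12 and the kinase Sik2 by -0.58 ± 0.12, with limma adjusted p-values from 0.011 to 0.042. Of the endocardial list, Npr3 was the 1 called member (median -0.18, camera adjusted p = 0.039, and adjusted p = 0.45 with an estimated correlation). Megakaryocyte and platelet genes had a median of 0.67 (camera adjusted p = 0.0041) and cardiomyocyte genes of -0.74 (camera adjusted p = 0.018), and with an estimated correlation these gave adjusted p = 0.55 and adjusted p = 0.45. Tip cell and sprouting, pan-endothelial, basement membrane, BMP and TGF-beta, VEGF and immediate-early genes passed camera as higher sets (medians 0.43, 0.31, 0.39, 0.26, 0.11 and 0.25). Cholesterol synthesis genes passed as a lower set (median -0.36). These lists had camera adjusted p = 0.24 to 0.48 with an estimated correlation. Notch1 and Notch2 differed by -0.24 ± 0.15 and 0.32 ± 0.15 (limma adjusted p = 0.52 and 0.40). In limma 56 genes were higher and 7 lower, and without scaling 52 were higher and 0 lower, where the 7 named falls kept log2 changes from -0.51 to -0.90 (limma adjusted p from 0.0558 to 0.144). The groups lie in different ranges of file numbers. As a covariate that range is estimated from +/− and +/vg alone, with 1 low library each. A call lost with it is therefore not by itself an effect of the range. With this covariate 19 genes were higher and 4 lower. Of the named falls Npr3 was then called (limma adjusted p = 0.0492), and Frem1, Slit2, Ccnd2, Pik3c2b, Lifr and Sik2 were not, with log2 changes from -0.41 to -0.78 (limma adjusted p from 0.258 to 0.669). The rises of Tpi1, Vegfa, Egln3, Ndrg1, Flt1 and Smad7 were not called either (limma adjusted p from 0.0678 to 0.480), at log2 changes of 1.29, 1.22, 1.97, 2.30, 0.87 and 0.64, with 1.32, 1.26, 2.00, 2.07, 0.84 and 0.77 before. Among the lists, megakaryocyte and platelet genes changed direction (camera adjusted p = 0.191). Pan-endothelial, basement membrane, immediate-early and BMP and TGF-beta genes did not pass (camera adjusted p = 0.0727, 0.0727, 0.0824 and 0.889). The count was 19 without 12/− replicate 1, 37 without replicate 2, 23 without replicate 3, 89 without +/+ replicate 1, 31 without +/+ replicate 2 and 30 without +/+ replicate 3.

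The comparison of 12/− with +/− sets a 12 allele against a wild-type allele opposite the deletion. Bnip3 rose by 3.03 ± 0.30 on the log2 scale, Adm by 2.60 ± 0.24, Ndufa4l2 by 2.55 ± 0.25, the glucose transporter Slc2a3 by 2.19 ± 0.30, the phosphodiesterase Pde4b by 2.16 ± 0.30, Egln3 by 2.15 ± 0.24, Sparcl1 by 2.11 ± 0.20, Ndrg1 and Bhlhe40 by 2.07 each and the stress-induced Ddit4 by 2.01 ± 0.39 (SE, limma adjusted p-values from 3.05e-04 to 0.041). Tpi1 rose from 70.9 to 222 scaled FPKM (n = 3 each, limma adjusted p = 3.05e-04). Igfbp3, a growth factor binding protein in the arterial and tip cell lists, rose from 30.3 to 99.8 scaled FPKM (limma adjusted p = 0.026), and Acvrl1, a BMP receptor, from 9.29 to 16.5 (limma adjusted p = 0.041). Of the 27 hypoxia and glycolysis genes 14 were called higher, and 24 adjusted over the list alone (median 1.06, camera adjusted p = 5.5e-36, and adjusted p = 0.011 with an estimated correlation). Hand2, a transcription factor of heart development, fell from 16.5 to 5.55 scaled FPKM (log2 change -1.38 ± 0.24, limma adjusted p = 0.021), and Alg14, Frem1, Ccnd2 and Pik3c2b changed by -0.70, -0.65, -0.62 and -0.57 (limma adjusted p-values from 0.039 to 0.041). The microRNA gene Mir374 also passed, though in 9 of 21 alternatives only, and it was listed at 0 in all 3 12/− libraries. Tip cell and sprouting, pan-endothelial, basement membrane and BMP and TGF-beta genes passed camera as higher sets (medians 0.28, 0.18, 0.26 and 0.20). Endocardial and cholesterol synthesis genes passed as lower ones (medians -0.28 and -0.38). These lists had camera adjusted p = 0.52 to 0.68 with an estimated correlation. In limma 54 genes were higher and 6 lower, and without scaling 38 were higher and 2 lower. Without scaling Alg14, Frem1, Ccnd2 and Pik3c2b were not called, at log2 changes of -0.71, -0.67, -0.64 and -0.59, nor were Ndrg1, Ddit4, Igfbp3 and Acvrl1, at 2.08, 2.01, 1.73 and 0.76 (limma adjusted p from 0.0592 to 0.205). With the number range as a covariate 35 genes were called. The named falls were then not called (limma adjusted p from 0.185 to 0.336), at log2 changes of -1.25, -0.68, -0.63, -0.61 and -0.42 for Hand2, Alg14, Frem1, Ccnd2 and Pik3c2b. Mir374 also lost its call, at -4.31 (limma adjusted p = 0.336). The rises of Ndrg1, Ddit4, Igfbp3, Vegfa and Acvrl1 were not called either (limma adjusted p from 0.0696 to 0.333), at 2.22, 1.38, 1.57, 1.23 and 0.63. Pan-endothelial, basement membrane and BMP and TGF-beta genes did not pass (camera adjusted p = 0.254, 0.0591 and 0.822). The count was 12 with the groups compared alone, 18, 34 and 25 without 12/− replicates 1, 2 and 3, and 156 without +/− replicate 3. Without the 2 shallow libraries, or without the shallow +/− replicate 2 alone, Hand2, Alg14, Frem1, Ccnd2, Pik3c2b and Mir374 were not called. Nor were Ndrg1, Ddit4, Igfbp3 and Acvrl1. All kept their direction, and the other named rises stayed called.

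Against the mean of the 4 normal groups, 76 genes were higher and 7 lower in 12/− in limma, and 81 higher and 0 lower without scaling. The 7 named falls had log2 changes from -0.39 to -0.62 without scaling (limma adjusted p from 0.0568 to 0.247). The largest rises were those of Adm (log2 fold change 2.72 ± 0.19, SE), Bnip3 (2.68 ± 0.24), Ndufa4l2 (2.28 ± 0.20), Ankrd37 (2.17 ± 0.26), Cav1 (2.09 ± 0.20), Bhlhe40 (2.06 ± 0.19), Egln3 (1.97 ± 0.19), Slc2a3 (1.85 ± 0.24), Sparcl1 (1.85 ± 0.16) and Kcne3 (1.75 ± 0.18), with limma adjusted p-values from 2.9e-05 to 0.0015. Of the hypoxia and glycolysis list 18 of 27 were called higher, and 26 adjusted over the list alone (camera adjusted p = 3.8e-48, and adjusted p = 0.0035 with an estimated correlation). Its mean log2 level lay between 5.74 and 5.95 in the 12/− libraries and between 4.39 and 5.03 in the 12 libraries of the normal groups. Nid2, a basement membrane protein, Flt1, Acvrl1 and Smad7 rose by 0.89, 0.74, 0.63 and 0.60 on the log2 scale (limma adjusted p-values from 0.0071 to 0.035). The genes called lower were Npr3 (-0.69 ± 0.12), Galt, an enzyme of galactose metabolism (-0.67 ± 0.13), Frem1 (-0.63 ± 0.10), Tusc2 (-0.54 ± 0.11), Pik3c2b (-0.51 ± 0.09), Ccnd2 (-0.49 ± 0.10) and Sik2 (-0.46 ± 0.09), with limma adjusted p-values from 0.0074 to 0.034. Arterial, tip cell and sprouting, pan-endothelial, basement membrane and BMP and TGF-beta genes passed camera as higher sets (medians 0.15, 0.37, 0.25, 0.34 and 0.21). Endocardial, interferon and cholesterol synthesis genes passed as lower ones (medians -0.23, -0.38 and -0.41). These lists had camera adjusted p = 0.20 to 0.71 with an estimated correlation. The count was 27 and 39 without 12/− replicates 1 and 2, 139 without +/− replicate 2, and 127 without +/− replicate 3. With the number range as a covariate it was 47. Of the named falls Npr3 was then called (limma adjusted p = 0.0283) and Galt, Frem1, Tusc2, Ccnd2, Pik3c2b and Sik2 were not (limma adjusted p from 0.0900 to 0.334), at log2 changes of -0.78, -0.61, -0.57, -0.48, -0.38 and -0.36. The rises of Igfbp3, Nid2, Flt1, Smad7 and Acvrl1 were not called either (limma adjusted p from 0.0670 to 0.276), at 1.44, 0.89, 0.76, 0.52 and 0.50. Arterial and BMP and TGF-beta genes did not pass (camera adjusted p = 0.521 and 0.50).

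**Figure D3:**
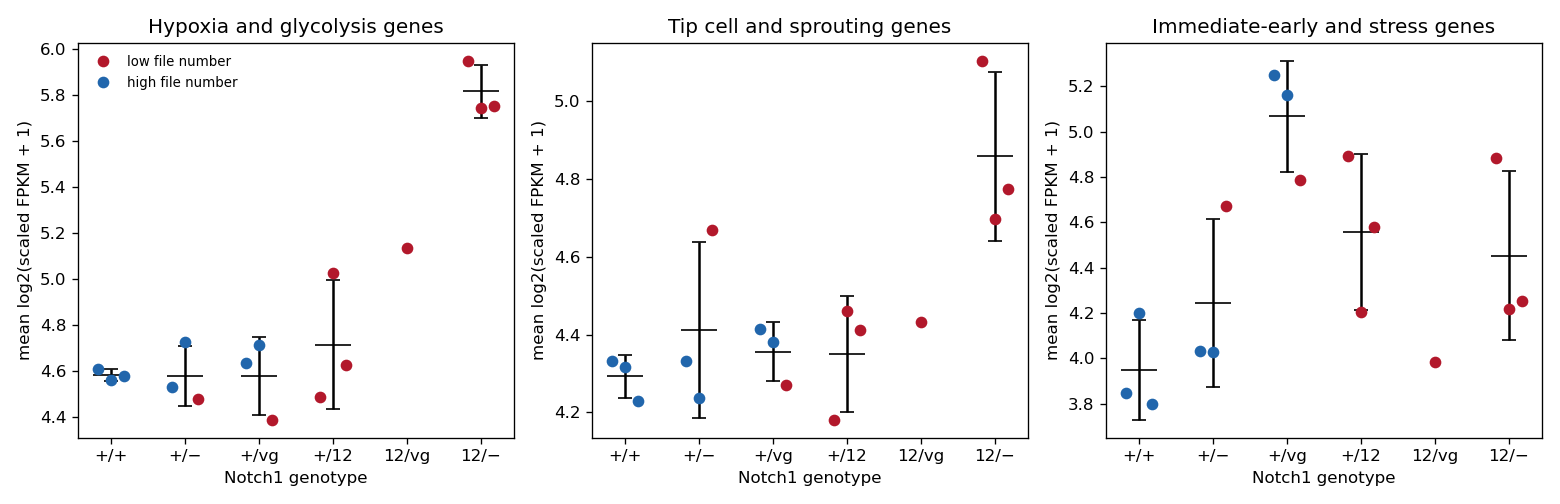
Mean log2(scaled FPKM + 1) over the genes of 3 lists (vertical axis) in each library by Notch1 genotype (horizontal axis), where points are libraries coloured by file number range and bars are means with SD for groups of 3. The 12/− libraries lie between 5.74 and 5.95 for hypoxia and glycolysis genes and the 12/vg library at 5.14, and for immediate-early and stress genes the +/vg libraries have the highest mean.

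Among the normal genotypes, no single gene was called for +/−, +/vg or +/12 against +/+, or for +/vg against +/−. In limma at an unadjusted p under 0.05 these comparisons had 793, 792, 566 and 890 genes. The 95% interval of the difference lay within 2-fold for 85.2%, 86.6%, 87.1% and 85.1% of genes. These intervals are on the scale of log2(scaled FPKM + 1), which understates the change of low genes. Values that did not pass included Clstn1, which averaged 1.04 ± 0.361 scaled FPKM in +/+ and 3.31 in +/−, 2.88 in +/vg and 2.97 in +/12 (n = 3 each, limma adjusted p = 0.094, 0.099 and 0.31). For +/− against +/+ the other smallest p-values were those of Ttc32 (log2 change 0.93 ± 0.16), Dnase1l1 (0.85 ± 0.15), Ppie (-0.88 ± 0.14), Pank1 (-0.79 ± 0.14) and the small nucleolar RNA Snora17 (-3.44 ± 0.73), with limma adjusted p-values from 0.16 to 0.42.

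For +/vg the immediate-early and stress list, genes such as Fos, Egr1 and Atf3 that respond within minutes to stimulation or handling, was higher than in +/+ (median log2 fold 1.18, with all 22 positive, camera adjusted p = 3.4e-20, and adjusted p = 0.096 with an estimated correlation) and than in +/− (median 0.86, all 22 positive, camera adjusted p = 9.9e-12, and adjusted p = 0.45 with an estimated correlation). No member was called over all genes tested. Adjusted over the list alone, 18 and 9 of 22 were higher. Against +/+, megakaryocyte and platelet genes (median 0.77), cholesterol synthesis genes (0.27) and cell cycle genes (-0.11) also passed camera, with camera adjusted p = 0.61 to 0.76 with an estimated correlation and 0.112 each with the number range as a covariate. The antiproliferative gene Btg2 of this list had values of 6.77 in +/+ and 19.1 in +/vg scaled FPKM (n = 3 each, limma adjusted p = 0.099). Pramef8 (0.87 ± 0.13), Spryd4 (-0.77 ± 0.13), Gngt2 (-0.78 ± 0.13) and Ppap2c (-0.99 ± 0.14) had limma adjusted p = 0.099 each against +/+. Against +/− the values of Hhex, a transcription factor of vascular and blood progenitors (1.10 ± 0.19), Gabarapl1 (0.73 ± 0.14), Ppap2c (-0.84 ± 0.14), Gngt2 (-0.76 ± 0.13) and Alg14 (-0.75 ± 0.13) did not pass (limma adjusted p from 0.24 to 0.27).

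For +/12 against +/+ the immediate-early and stress list had a median of 0.67 (camera adjusted p = 1.3e-07, and adjusted p = 0.74 with an estimated correlation). Megakaryocyte and platelet genes had a median of 1.01 (camera adjusted p = 2.1e-08, and adjusted p = 0.74 with an estimated correlation) and cardiomyocyte genes of -0.98 (camera adjusted p = 0.0025, and adjusted p = 0.74 with an estimated correlation). Haemogenic progenitor and basement membrane genes passed at camera adjusted p = 0.0496 each (medians 0.11 and 0.20), and gave adjusted p = 0.74 and adjusted p = 0.83 with an estimated correlation. These groups do not share a range of file numbers. With that range as a covariate the platelet and basement membrane lists went in the other direction (camera adjusted p = 0.97 and 0.235). Haemogenic progenitor genes did not pass (camera adjusted p = 0.353). Hypoxia and glycolysis genes (median 0.09, camera adjusted p = 0.158) passed as a higher set with the covariate (camera adjusted p = 2.7e-05). The values of Prkcc (1.44 ± 0.29), Was (0.94 ± 0.18), Pde7a (-0.63 ± 0.15), Acyp1 (-0.80 ± 0.19) and Myl2, a cardiac myosin light chain (-2.27 ± 0.53), did not pass (limma adjusted p = 0.86 each).

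Over the number of wild-type alleles (0, 1 or 2 in all 16 libraries), Npr3 rose by 0.47 ± 0.07 per allele on the log2 scale (SE, limma adjusted p = 0.016), while the glycolytic enzyme Pfkp, Kcne3 and Cav1 changed by -0.67 ± 0.10, -1.01 ± 0.15 and -1.11 ± 0.19 per allele (limma adjusted p = 0.016, 0.016 and 0.042). The slopes of Tmem69 (0.37) and Pik3c2b (0.33) did not pass (limma adjusted p = 0.0698 and 0.0595). The hypoxia and glycolysis list had a median slope of -0.48 (camera adjusted p = 8.9e-23, and adjusted p = 0.24 with an estimated correlation). Its mean log2 level was 4.58 in +/+, 4.58 in +/−, 4.58 in +/vg and 4.71 in +/12, and 5.14 in 12/vg and 5.82 in 12/−. The clear step thus lay at 12/−. The 12/vg value is that of 1 shallow library, close to the highest normal library at 5.03. The groups without a wild-type allele all carry a 12 allele. Tip cell and sprouting, pan-endothelial, basement membrane and BMP and TGF-beta genes also had slopes below 0 (medians -0.18, -0.16, -0.18 and -0.08) and cardiomyocyte and cholesterol synthesis genes above 0 (medians 0.38 and 0.17), with camera adjusted p = 0.24 to 0.46 with an estimated correlation. The BMP and TGF-beta list did not pass with the number range as a covariate (camera adjusted p = 0.763). In limma 4 genes were called, with 0 called with the number range as a covariate, 0 without scaling, 0 without a filter and 0 without any single 12/− replicate. With the number range the slopes of Npr3, Pfkp, Kcne3 and Cav1 were 0.57, -0.59, -1.01 and -0.89 (limma adjusted p from 0.0968 to 0.405), and without scaling 0.45, -0.69, -1.04 and -1.13 (limma adjusted p from 0.0564 to 0.0810). In contrast, 20 genes were called without the 12/vg library, 48 without +/− replicate 2, 40 without +/+ replicate 1, 9 without +/+ replicate 2 and 7 without +/− replicate 1.

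The 12/vg library, the only one of its genotype, has no replicate check, and it was among the shallow libraries. Its mean level of the hypoxia and glycolysis list was 5.14, above the highest normal library at 5.03 and below the lowest 12/− library at 5.74. Of the 76 genes higher in 12/− against the mean of the normal groups, 33 lay above all 12 normal libraries in 12/vg, 41 within their range and 2 below. These genes were picked against the same normal libraries. The share of all genes tested that lay above them in 12/vg was not counted, so the 33 have no reference value. The median difference of these 76 genes from the normal libraries was 0.35 on the log2 scale in 12/vg, and 1.02 in 12/−. Of the 7 genes lower in 12/−, 6 lay within the normal range in 12/vg and 1 below, with a median difference of -0.04 in 12/vg and -0.54 in 12/−. Among the normal libraries +/12 replicate 2 had the highest such difference, at 0.32. Adm was at 2.46, Bnip3 at 7.77 and Kcne3 at 47.7 scaled FPKM in 12/vg, and Ndufa4l2 was listed at 0.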

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

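The tests of the hypoxia pattern by number range, by library composition and by cells of other types, and the alternatives with depth and without the shallow libraries, were chosen after the results were seen. The effect of the null allele differed between embryos with a 12 allele and with a wild-type allele opposite it, tested as an interaction in limma, for 5 genes. The interaction was 2.30 on the log2 scale for Adm (limma adjusted p = 0.0455), 2.27 for Ndufa4l2 (0.0480), 1.64 for Tpi1 (0.0332), 1.29 for Plod2, a lysyl hydroxylase of collagen (0.0287), and 1.12 for Ero1l (0.0455). At an unadjusted p under 0.05 limma had 694 genes. The count of 5 was 1, 1 and 0 without 12/− replicates 1, 2 and 3, 0 without +/12 replicate 3, 9 and 0 without +/− replicates 1 and 2, and 0 and 3 without +/+ replicates 2 and 3. Of the gene lists, hypoxia and glycolysis genes had a median interaction of 1.09 (camera adjusted p = 3.2e-28, and adjusted p = 0.027 with an estimated correlation). Tip cell and sprouting genes had a median of 0.31, cholesterol synthesis genes of -0.35, immediate-early and stress genes of -0.34 and megakaryocyte and platelet genes of -0.64, and each of these 4 passed camera with the preset correlation alone, with an adjusted p of 0.86 to 0.87 with an estimated correlation. With the number range as a covariate the megakaryocyte and platelet list did not pass (camera adjusted p = 0.399). No gene was called with the file number range as a covariate, with depth as a covariate, without scaling, or without the 2 shallow libraries. Over all alternatives run the interaction stayed above 0, from 2.10 to 2.67 for Adm, 2.16 to 4.14 for Ndufa4l2, 1.48 to 1.76 for Tpi1, 1.22 to 1.47 for Plod2 and 1.02 to 1.23 for Ero1l on the log2 scale, and the hypoxia and glycolysis list passed with the number range, without scaling and without the shallow libraries (camera adjusted p = 8.1e-23, 1.2e-29 and 6.7e-35).

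Higher hypoxia and glycolysis genes in 12/− were weighed against technical explanations. A difference between ranges of file numbers would leave no difference within a range, but the median log2 fold of the list between 12/− and +/12, all in the low range, was 0.944 (quartiles 0.711 and 1.40). Depth as a covariate left it at 0.938 (quartiles 0.711 and 1.40). These values argue against either as the whole cause. Library composition also moved with the group. Ribosomal protein genes held 31.7 to 32.8% of the summed FPKM in the 12/− libraries and 27.1 to 30.6% in the 13 others. Mtrnr2l held 4.26 to 5.65% in 12/− and 7.69 to 9.32% in +/12. Over the 13 others it held 4.51 to 9.32%, which overlaps 12/−. The mean log2 level of the list differed by 1.10 between 12/− and +/12 (95% interval 0.801 to 1.41). The difference was 1.23 with the ribosomal protein share as a covariate (95% interval 0.803 to 1.65) and 1.07 with the Mtrnr2l share (95% interval 0.528 to 1.62). These values argue against a linear effect of either share as the whole cause. The ribosomal protein shares of 12/− and the others do not overlap, so that correction reaches beyond the shares seen in the others. Cells of other types could bring such transcripts past the CD31 sort. Over 8 of the 9 lists of other cell types the highest median between 12/− and +/12 was 0.0948, for neural genes. This argues against cells of these 8 types as the whole cause of the rise against +/12. Against +/+ and +/−, megakaryocyte and platelet genes had the highest medians of the 8, at 0.67 and 0.41. Cardiomyocyte genes had the lowest, at -0.74 and -0.36. With the number range as a covariate the megakaryocyte and platelet medians were -0.28 and -0.24. Whether such cells add to the rise against +/+ or +/− was not tested. The list for epithelium and endoderm was set apart from the 8 after its values were seen. Its median was 0.323 (quartiles 0.0588 and 0.526), above the bound of 0.3 for excluding it and under the hypoxia list. Against +/+ its median was -0.15, and 0.90 with the number range as a covariate, where it passed camera as a higher set (adjusted p = 0.0298). Against +/− its median was -0.35, and 0.29 with that covariate. Its mean log2 level ran from 1.53 to 1.93 in the 12/− libraries and from 1.00 to 3.12 in the 12 normal libraries. Normal libraries thus reached higher levels of this list, while their hypoxia level was at most 5.03 and that of 12/− at least 5.74. Of that list Krt18, its most abundant member, differed by 0.33 ± 0.69 on the log2 scale between 12/− and +/12 (SE, limma adjusted p = 1.0). Given the median of 0.323 against +/12 and the higher set with the covariate, a share of such cells stays open. That genotype acts on these genes in the cells, or through the state of the embryo, was not tested apart and stays open as a hypothesis.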

How the results depend on the processing

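No paired analysis was possible because the labels give no replicate numbers shared between groups. Low depth limits low FPKM values in +/− replicate 2 and 12/vg. Alternatives that left out the shallow libraries, added depth, kept genes of another status or left out short transcripts were chosen after seeing the data. Named genes that were called kept their direction under every alternative run. Without scaling the median over all genes shifted by 0.11 for 12/− against +/12. Of the named genes' results over all alternatives 2797 kept their direction and stayed on the same side of the threshold. These include genes called in neither fit, so 2797 is not a count of calls that held. A call was lost in 426 and gained in 19, and 16 changed direction with no call in either fit. Unless stated, the cause of a change was not tested.

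For 12/− against +/12 (22 genes), 92 were called with array weights, 34 with robust moderation, 35 with the number range, 36 with depth, 8 with the groups compared alone (fewer libraries), 37 without short transcripts and 41 without the shallow libraries, and 10 to 30 leaving out a replicate. Against +/+ (63), the counts were 143 with array weights, 23 with the number range, 121 with depth, 115 without the shallow libraries, and 19 to 89 leaving out a replicate. Against +/− (60), they were 35 with the number range, 12 with the groups alone, and 18 to 156 leaving out a replicate. Against the mean of the normal groups (83), they were 249 with array weights, 47 with the number range, 149 with depth, 139 without the shallow libraries, and 27 to 139 leaving out a replicate. All 22, 63 and 83 genes called against +/12, +/+ and the mean were among those called without the shallow libraries. Against +/− the named falls and the rises of Ndrg1, Ddit4, Igfbp3 and Acvrl1 were not called there.

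For the normal genotypes, where 0 genes were called, +/− against +/+ gave 1 without a filter, 4 with the groups alone and 0 to 4 leaving out a replicate. The +/vg against +/+ comparison gave 3 with array weights, 1 without a filter, 1 with the groups alone and 0 to 3 leaving out a replicate. The +/vg against +/− comparison gave 1 without a filter, 2 with the groups alone and 0 to 4 leaving out a replicate. The +/12 against +/+ comparison gave 1 with the number range and 0 to 2 leaving out a replicate.

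The interaction (5 genes) gave 0 without scaling, 0 with the number range, 0 with depth, 0 without the shallow libraries, 2 with array weights, 3 at a mean FPKM of at least 5, 1 with the groups alone, 2 at a pseudocount of 0.1, 1 with quantile normalization and 0 to 9 leaving out a replicate. The wild-type allele trend (4 genes) gave 0 without scaling, 0 without a filter, 0 with the number range, 107 with array weights, 144 with depth, 21 at a mean FPKM of at least 5, 25 without short transcripts, 66 without the shallow libraries and 0 to 48 leaving out a replicate.

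Over all comparisons 57 list tests passed (37 higher, 20 lower). With an estimated correlation 5 passed, all for hypoxia and glycolysis genes, and without scaling 65 passed (35 higher, 30 lower). With the number range 53 passed, 38 of them shared with the 57. Megakaryocyte and platelet genes then changed direction in 12/− against +/+ (adjusted p = 0.19), in 12/− against the mean (0.024), in +/12 against +/+ (0.97) and in the wild-type allele trend (0.022), and basement membrane genes in +/12 against +/+ (0.24).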

Other observations

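The tests of number range and of neighbouring numbers for +/vg, the test of counting noise and the test of Snora17 were chosen after the results were seen. Gene lists for blood and muscle cells varied widely among the normal libraries. The mean log2 level of megakaryocyte and platelet genes ran from 2.82 to 5.02 over the 12 normal libraries, and that of cardiomyocyte genes from 1.16 to 2.94. Cell cycle genes ran from 4.51 to 4.74 and mitochondrial respiration genes from 6.55 to 6.80. Notch targets ran from 3.66 to 4.08 in the normal libraries and from 3.80 to 4.05 in the 12/− libraries.

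Other splits of the same libraries were fitted in the same way. For the comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real split called 22 genes for 12/− against +/12, 63 against +/+ and 60 against +/−, 1 of 10 splits reached each of these, and the highest other splits called 1, 0 and 1. Among normal genotypes the real split called 0 (limma, with 566 to 890 genes at an unadjusted p under 0.05). Any split reaches a count of 0, so the 10 of 10 that did so carry no information. The highest others called 2 for +/−, 3 for +/vg and 2 for +/12 against +/+, and 2 for +/vg against +/−. Against the mean of the normal groups 1 of 100 splits, the real one, reached 83 genes, and the highest other called 5. For the interaction 1 of 100 reached 5 genes, and the highest other called 3. For the trend 2 of 100 reached 4 genes, and the highest other called 10, more than the real split. For the mean of the normal groups the share was under 0.05, which argues against a chance assignment of libraries to groups. That holds only if libraries are independent and could be exchanged between groups, which the labels do not show. All 12/− libraries lie in the low range of file numbers, and the normal groups hold both ranges. For the interaction and the trend the share was also under 0.05. Their splits shuffled all genotypes compared, so a difference of 12/− alone could set the real split apart. They therefore do not decide whether an interaction or a slope arose by chance. The splits take no account of the file number range, with which as a covariate 0 genes were called for the interaction and 0 for the trend.

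Immediate-early and stress genes were higher in +/vg as a set with the preset correlation in camera, with adjusted p = 0.096 against +/+ and 0.45 against +/− with an estimated correlation, and no member was called over all genes. Within the high range of file numbers the median log2 fold of the list against +/+ was 1.27 (quartiles 0.789 and 1.53, 2 against 3 libraries, 22 of 22 genes positive), which argues against the number range as the whole cause. Against +/− it was 1.08 within the high range (2 against 2) and 0.34 within the low range (1 against 1, 17 of 22 positive). Handling shared by libraries of neighbouring file numbers would make neighbours alike. Over 15 libraries, neighbours differed by 0.405 on average and shuffled orders by 0.312 (permutation p = 0.971, one-sided, 100000 shuffles). Neighbours often share a group, and values less their group mean are pushed apart by that step, so this p excludes nothing although it lies past the bound of 0.5 first written for it, and handling of whole groups cannot be told apart from genotype.

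The 2 shallow libraries stood apart from the other 14 on the first component, which held 16.1% of the variance, at 58.2 and 52.1 against values from -18.8 to 8.43. On the second component +/+ replicate 1, whose label is spelled differently, lay at -0.836 and +/+ replicates 2 and 3 at -36.3 and -27.3. Counting noise that is independent between the 2 shallow libraries would leave their deviations unrelated. Across 2113 genes with a mean FPKM of at least 20 their deviations from separate sets of libraries correlated at 0.511. Those of 45 pairs of deeper libraries correlated at -0.164 to 0.158. These are correlations across genes, which are not independent replicates. Genes were filtered on FPKM and not on fragments, and deeper libraries cannot show what low depth does. An effect of low depth shared by both libraries therefore stays open. Transcript length may contribute, with a Spearman rho of 0.169 between mean deviation and length, which lies between the bounds set beforehand and leaves this open. No biological explanation was tested, since the 2 libraries differ in genotype.

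Sequence carried along with the edited alleles could change genes near Notch1, as a hypothesis. Of 181 genes tested within 10 megabases of it, 17 (9.39%) had an unadjusted p under 0.05 in 12/− against +/+, and of the 10369 others 1271 (12.3%) did (Fisher's exact p = 0.302, two-sided, odds ratio 0.742, 95% interval 0.421 to 1.23). The lower share met the bound written beforehand for excluding this, but that bound took no account of the error, and the interval includes 1, so neither an excess nor its absence was shown.

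Snora17, a small nucleolar RNA gene of 132 nt that lies 135 kilobases from Notch1 (chromosome 2, 26494710 to 26494841, mm9), ran from 0 to 12.6 scaled FPKM in the 6 libraries with a null allele and from 33.1 to 72.1 in 9 of the 10 others, and it was listed at 0 in the shallow 12/vg library (exact permutation p = 0.017 over all 16 libraries, unadjusted and on a gene picked for this difference among 10550). FPKM of so short a transcript is imprecise, and +/− replicate 2, among the libraries with a null allele, was shallower than 12/vg.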
